A study of Homo sapiens with 12 samples.

How the data were processed

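The data were 12 RNA sequencing libraries of MCF7 cells in 4 groups of 3: cells with ectopic WT MED1 or ectopic 6KQ MED1, each untreated or given 0.5 mM H2O2 for 6 h. Groups and replicate numbers were taken from the labels, which do not spell out 6KQ. The series' design text describes depletion of endogenous MED1 for cells with another mutant, and the column names of the table carry KO, but no source used here states it for these cells.

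Per the labels' protocols, cells were washed and flash frozen, RNA was isolated with a QIAGEN RNeasy kit, and stranded TruSeq libraries were made from polyadenylated RNA. The authors deposited 1 table of raw counts per gene for the human genome and for Drosophila biarmipes, whose material the labels describe as a spike-in. When the spike-in was added and in what amount is not given in the sources used here. STAR 2.5.2b, SAMtools 1.10, DESeq2 1.32.0 and the hg38 build were named per the submitters' processing notes, with no role or order. The counting tool, the annotation and the strand setting are not given in the sources used here, so antisense genes, overlapping genes and near-identical copies are reported as uncertain. Stranded polyadenylated libraries favour long, polyadenylated transcripts, and counts per gene grow with transcript length, so levels were compared between libraries and not between genes.

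Each column of the table was matched to a sample by its name, and 0 columns were left unused. The 25186 human genes were identified by NCBI Gene ID. Of these, 25081 matched a RefSeq gene table of GRCh38.p14, which gave symbols and coordinates, and 105 did not, holding 0.0669% of human counts. Totals ran from 26381495 to 31954933 counts per library, with 17212 to 17377 human genes detected untreated and 18613 to 18755 after H2O2. Ribosomal RNA took 0.0560% to 0.159% of human counts. Reads carry no molecular identifiers in the sources used here, so copies made by amplification stay in the counts. Counts can therefore vary by more than sampling error.

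Human counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 4 groups (minimum count 10), which left 14999 genes, TMM scaling, robust quasi-likelihood fits and F tests in 1 model of all 12 libraries, with no covariates. The contrasts were 6KQ against WT untreated, 6KQ against WT after H2O2, H2O2 against untreated in each line, and the interaction. Adjusted p-values are Benjamini-Hochberg within each contrast at a threshold of 0.05. The SE given with a log2 fold change is its size divided by the square root of the F statistic. It is not a standard error of the fitted coefficient, and it may be too small for genes with few counts. The 2 responses to H2O2 share no libraries, nor do the 2 comparisons of 6KQ with WT. Mean CPM values are TMM-scaled, except MED1 per library, which is CPM of human counts.

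The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named were MED1, and for each contrast the 6 largest rises and 6 largest falls (5 and 5 for the interaction). These were taken among genes with an adjusted p under 0.05 and a mean of at least 5 CPM in the higher group. Every contrast but the interaction also required no overlap between the 3 and 3 libraries, a separation that chance gives for 10% of genes. For each list with at least 3 members past the threshold, the 3 with the smallest adjusted p were added. Antisense and pseudogene symbols were kept. Outside the rule, members spelled out where a list had 5 or fewer changed genes, and 6 interaction genes that passed without untreated WT replicate 2, were chosen after their values were seen. The rule also allowed 1 member per list that did not pass; 69 such members were left unnamed after many were seen to change sign with spike-in scaling.

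Of 28 fixed lists, 27 were tested: Mediator subunits, NRF2 targets, p53 targets, ATF4 stress response, unfolded protein response chaperones, heat shock, immediate early genes, metallothioneins and zinc response, NF-kB, interferon-stimulated genes, estrogen receptor targets, luminal, basal and mesenchymal, and leukocyte and endothelial markers, hypoxia targets, S phase, G2 and M phase, replication-dependent histones, cholesterol synthesis, apoptosis, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, autophagy and lysosome, DNA repair, non-polyadenylated RNA and nuclear long noncoding RNA. Mitochondrially encoded mRNAs were not analysed here, since 0 of 13 members matched the table. The lists hold 980 genes, 28 of them in more than 1 list. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted over 135 list tests, and again with the correlation estimated for each list. By that estimate 3 of 11 calls held for untreated 6KQ against WT, 4 of 12 after H2O2, 7 of 17 for H2O2 in WT cells, 7 of 15 for H2O2 in 6KQ cells and 2 of 10 for the interaction.

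The pipeline was tested on simulated counts with 200 changed genes. At the spread of the 12 libraries it recovered 58.2%, 98.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale for H2O2 in 6KQ cells (14681 genes), and 26.9%, 94.0% and 100% for the interaction (14662 genes), with 7 of 178 and 6 of 153 calls false. At the spread without untreated WT replicate 2 the shares for a change of 0.5 were 100% (14783 genes) and 88.1% (14767 genes), with 17 of 217 and 13 of 205 calls false. Simulated counts were independent between genes, with the dispersion of a gene alike in every library. In the data untreated WT replicate 2 set much of the spread, with a shift shared across genes. Recovery and false calls at the spread of 12 libraries may therefore not hold for the real fit.

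Alternatives were DESeq2 1.42.0, RLE, upper-quartile and spike-in scaling, no filter and a filter of 5 CPM in 3 libraries, the compared groups alone, the replicate number as a block, non-robust dispersion, a test against a fold change of 1.2, and each library left out in turn. Added after the data were seen were voom with sample quality weights, and untreated WT replicate 2 left out together with spike-in scaling, with an estimated correlation or with the compared groups alone. List counts under each scaling were also tabulated after the results were seen.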

Results

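Polyadenylated RNA was sequenced from MCF7 cells, an estrogen receptor-positive human breast cancer line, that expressed an introduced copy of MED1. MED1 is the Mediator subunit through which nuclear receptors contact the transcription machinery. The introduced copy was either wild-type (WT) MED1 or a mutant that the labels call 6KQ, in a series concerned with MED1 acetylation. Each line was left untreated or given 0.5 mM H2O2 for 6 h, which made 4 groups of 3 libraries. The deposited table gave raw counts for 25186 human genes and for 17058 genes of Drosophila biarmipes, which the labels describe as a spike-in. Total counts ran from 26381495 to 31954933 per library, and the spike-in took 0.481% to 0.940% of them. Nothing in the labels states that the 3 replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

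MED1 itself (Gene ID 5469, chromosome 17, 39404285 to 39451263 on GRCh38) was abundant in every library. In CPM of human counts, untreated WT replicates 1, 2 and 3 held 1211, 569 and 1220, and untreated 6KQ replicates held 1210, 1241 and 1225. After H2O2 the WT replicates held 1115, 1205 and 1206, and the 6KQ replicates 1219, 1244 and 1194. MED1 did not pass the test between lines, at 0.27 ± 0.19 untreated and 0.07 ± 0.19 after H2O2, or -0.23 with spike-in scaling (log2 ± SE, n = 3 per group; edgeR quasi-likelihood adjusted p = 0.406 and 0.924). Its difference after against before H2O2 was 0.16 ± 0.19 in WT cells, or -0.12 with spike-in scaling, and -0.04 ± 0.19 in 6KQ cells (adjusted p = 0.506 and 0.869). Without untreated WT replicate 2 the WT value was -0.09 (adjusted p = 0.00619), and the untreated difference between lines was 0.02 (adjusted p = 0.686). With spike-in scaling the 6KQ value was -0.84 (adjusted p = 0.00241). Counts per gene do not separate WT from 6KQ MED1 or the introduced from the endogenous transcript.

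Untreated WT replicate 2 stood apart from every other library. The chi-square per gene of its pairs with WT replicates 1 and 3 was 126 and 117, against 1.80 to 4.21 for all other pairs within a group. Cytosolic ribosomal protein mRNAs took 7.94% of its human counts, against 4.93% to 6.11% elsewhere, and KRT8, a luminal keratin, took 2.08% against 1.16% to 1.48%. On principal components of log2 CPM, H2O2 set the first axis (79.1% of the variance), with untreated libraries at -53.7 to -51.2 and H2O2 libraries at 50.8 to 54.4. This library lay at -48.8 on the second axis (7.71%), where the others lay between -6.85 and 15.9. It was kept in the fit of 12 libraries, and counts of genes and lists without it are given for each comparison.

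**Figure D1:**
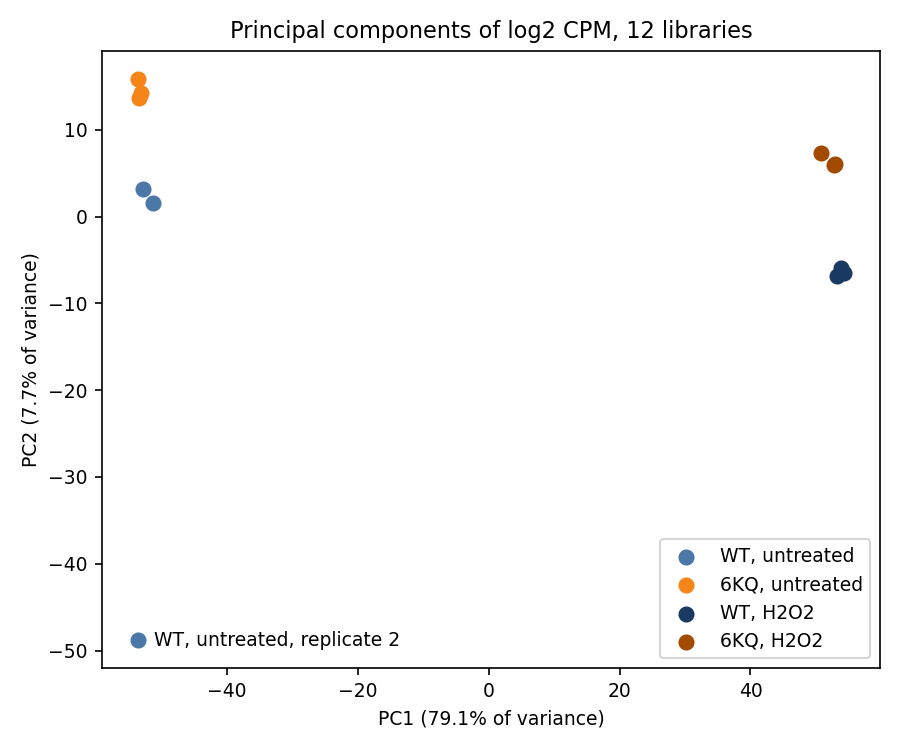
Each point is 1 of the 12 libraries, placed by its first (79.1% of variance) and second (7.71%) principal components of log2 CPM and coloured by group. Untreated libraries sit at -53.7 to -51.2 on the first axis and H2O2 libraries at 50.8 to 54.4, and untreated WT replicate 2 sits alone at -48.8 on the second.

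Scaling by the spike-in in place of TMM moved the median log2 value of all genes. The shift was 0.25 for 6KQ against WT untreated, -0.30 for 6KQ against WT after H2O2, -0.24 for H2O2 in WT cells, -0.79 for H2O2 in 6KQ cells and -0.55 for the interaction. Human counts per spike-in count were 173 ± 8.53 in untreated WT cells, 201 ± 8.08 in untreated 6KQ cells, 138 ± 11.4 in WT cells after H2O2 and 113 ± 7.49 in 6KQ cells after H2O2 (SD, n = 3). The libraries did not overlap in any of the 4 comparisons between groups. The exact two-sided permutation p was 0.1 for each, the smallest that 3 libraries against 3 allow, since chance alone separates 3 from 3 in 10% of arrangements. The difference between the lines in their change with H2O2 was -0.50 on the log2 scale. Shuffling the line labels within each treatment gave an exact permutation p of 0.005, the smallest that 400 arrangements allow. Its null is no difference between the lines in either treatment, so it does not test equal change with H2O2 alone. All changes below are relative to the bulk of human mRNA (TMM scaling). For each list that passed and each gene named, the value with spike-in scaling stands beside it where its sign turned. Among lists that did not pass, the sign of the median turned in 11 of 16 untreated, 7 of 15 after H2O2, 4 of 10 for H2O2 in WT cells, 7 of 12 for H2O2 in 6KQ cells and 11 of 17 for the interaction.

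**Figure D2:**
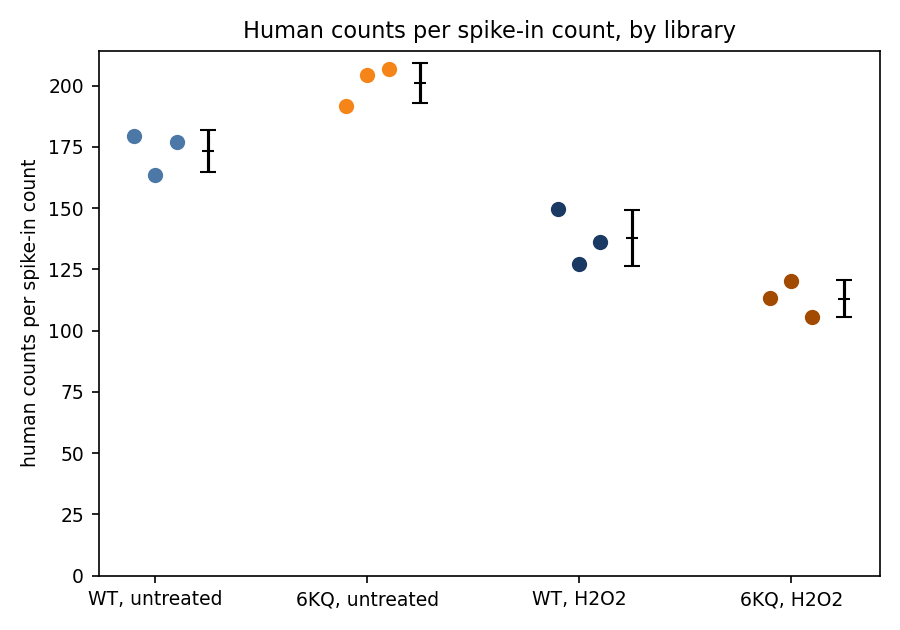
Human counts per spike-in count are plotted for each of the 12 libraries by group, with the mean and SD of 3 libraries. Group means were 173, 201, 138 and 113 for untreated WT, untreated 6KQ, WT after H2O2 and 6KQ after H2O2.

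The first question was how mRNA levels differed between untreated cells of the 6KQ and WT lines. The labels give no second line for either form of MED1. An effect of the form therefore cannot be told apart from other differences between the lines, here or after H2O2. Among the 6 genes that the naming rule gave as largest rises in 6KQ cells, keratin genes came first, and no keratin list was tested. KRT81 (Gene ID 3887, chromosome 12, 52285913 to 52291534) and KRT86, which encode hair keratins, rose by 2.07 ± 0.21 and 2.14 ± 0.12 (adjusted p = 0.000279 and 3.63e-06). KRT17, a keratin of basal epithelium, rose by 1.60 ± 0.21 (adjusted p = 0.00184). OLFML3 (Gene ID 56944, chromosome 1, 113979474 to 113982253), a secreted matrix protein, rose by 1.53 ± 0.06, from 9.02 ± 0.271 to 26.2 ± 0.426 CPM (SD, n = 3). ACTG2 (Gene ID 72, chromosome 2, 73893008 to 73919865), a smooth muscle actin, rose by 1.44 ± 0.13 and PHACTR1, an actin and phosphatase regulator, by 1.23 ± 0.11. The 6 largest falls by that rule included AKR1C2 (Gene ID 1646, chromosome 10, 4987775 to 5018000), AKR1C1 and AKR1C3, aldo-keto reductases of steroid metabolism, which stood at -1.33 ± 0.13, -1.08 ± 0.17 and -1.06 ± 0.13 (adjusted p = 0.000297, 0.00517 and 0.000931). The others were FCGRT, the neonatal Fc receptor, which fell by 1.19 ± 0.16, VAT1L, by 1.04 ± 0.12, and CLEC3A (Gene ID 10143, chromosome 16, 78022548 to 78032101), a C-type lectin, by 0.99 ± 0.14. The AKR1C genes and the keratin genes have near-identical relatives, and KRT81 and KRT86 overlap, so the split of reads within each family is uncertain.

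Estrogen receptor targets were higher in untreated 6KQ cells. Of 47 measured, 14 rose and 33 did not pass (22 rose adjusted over the list alone), with a median of 0.21 (camera adjusted p = 1.57e-12, and adjusted p = 0.000492 with an estimated correlation). CXCL12, a chemokine, rose by 0.64 ± 0.06, PDZK1, a scaffold protein, by 0.78 ± 0.08 and HSPB8, a small heat shock protein, by 0.68 ± 0.08. Of 51 genes of G2 and M phase 11 fell and 40 did not pass (22 fell adjusted over the list alone), and the list median was -0.18, or 0.08 with spike-in scaling, under which 1 of the 51 fell (camera adjusted p = 1.06e-08, and adjusted p = 0.00478 with an estimated correlation). Among them CDC25C, the phosphatase that activates CDK1, fell by 0.60 ± 0.09, TPX2, a spindle assembly factor, by 0.29 ± 0.05 and CCNB1, cyclin B1, by 0.47 ± 0.08. In cholesterol synthesis 2 of 32 genes fell, INSIG1 and IDI1, and 30 did not pass (7 fell adjusted over the list alone), and the list median was -0.15, or 0.09 with spike-in scaling (camera adjusted p = 1.64e-05, and adjusted p = 0.00719 with an estimated correlation). INSIG1, a sensor of sterol level, stood at -0.41 ± 0.05 and IDI1, an isoprenoid enzyme, at -0.28 ± 0.07, and both were named after their values were seen.

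A further 8 lists passed camera in untreated cells and lost the call with an estimated correlation. In the p53 targets 5 of 40 genes fell and 35 did not pass (1 rose and 5 fell adjusted over the list alone), and the list median was -0.17, or 0.08 with spike-in scaling (camera adjusted p = 0.00506, and adjusted p = 0.0587 with an estimated correlation). CCNG1, cyclin G1, stood at -0.27 ± 0.05, BTG2, an antiproliferative factor, at -0.32 ± 0.06 and CMBL, a hydrolase, at -0.20 ± 0.05, or 0.05 with spike-in scaling. Of 35 NRF2 antioxidant targets, 2 rose, 5 fell and 28 did not pass (2 rose and 9 fell adjusted over the list alone), with a median of -0.16, or 0.12 with spike-in scaling (camera adjusted p = 0.00556, and adjusted p = 0.499 with an estimated correlation). Those that fell were the 3 AKR1C genes, NQO1, a quinone reductase, and UGDH, an enzyme of glucuronate synthesis, which fell by 0.61 ± 0.06. Of 36 ATF4 stress-response genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone), with a median of -0.13, or 0.13 with spike-in scaling (camera adjusted p = 0.013, and adjusted p = 0.55 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell by 0.74 ± 0.09, PSPH, a serine synthesis enzyme, by 0.37 ± 0.06 and CBS, cystathionine synthase, by 0.34 ± 0.06. Of 33 interferon-stimulated genes 6 rose and 27 did not pass (14 rose and 1 fell adjusted over the list alone), with a median of 0.39 (camera adjusted p = 3.17e-06, and adjusted p = 0.257 with an estimated correlation). OAS3, an antiviral synthetase, rose by 0.56 ± 0.10, STAT1 by 0.35 ± 0.06 and SAMD9 by 1.78 ± 0.35. Of 40 replication-dependent histone genes 9 fell (13 adjusted over the list alone), H2BC5 by 0.87 ± 0.11, H3C10 by 0.70 ± 0.12 and H3C4 by 0.69 ± 0.12. The median was -0.41 (camera adjusted p = 1.18e-06, and adjusted p = 0.303 with an estimated correlation). Histone genes are near-identical copies, so these counts are uncertain. Of 21 basal and mesenchymal markers 5 rose and 2 fell (7 and 4 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0148, and adjusted p = 0.0704 with an estimated correlation). LAMC2, a laminin chain, rose by 0.99 ± 0.08 and CD44, a hyaluronan receptor, by 0.58 ± 0.07, while the collagens COL1A1 and COL6A1 were those that fell. Cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation genes had medians of -0.37 and -0.33 (camera adjusted p = 3.24e-10 and 1.03e-09, and adjusted p = 0.589 and 0.583 with an estimated correlation), and -0.04 and -0.03 without untreated WT replicate 2, the library rich in ribosomal protein mRNA. Of the 78 ribosomal protein genes 0 passed by edgeR, 36 were lower at an unadjusted p under 0.05, and 2 were lower by DESeq2. SDHD was the 1 of 75 oxidative phosphorylation genes that fell.

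The other 16 lists did not pass in untreated cells, with adjusted p of 0.143 for unfolded protein response chaperones (1 rose, HYOU1), 0.315 for S phase, 0.361 for autophagy (2 rose, ULK1 and WIPI1), 0.434 for heat shock (2 rose, HSPB8 and HSPH1), 0.472 for NF-kB (1 fell, ICAM1), 0.476 for Mediator subunits (1 fell, MED11) and 0.996 for leukocyte and endothelial markers. Immediate early genes (adjusted p = 0.505) split, with ZFP36, an mRNA decay factor, at 0.29 ± 0.06 and NR4A1, a nuclear receptor, at -0.45 ± 0.11. Luminal markers (median -0.09, or 0.18 with spike-in scaling; adjusted p = 0.84) also split: TFAP2C rose by 0.27 and MUC1 by 0.36, and ERBB2 stood at -0.18, or 0.07 with spike-in scaling. Hypoxia targets (median -0.04, or 0.21 with spike-in scaling; adjusted p = 0.738) included SLC2A1, a glucose transporter, at 0.31 ± 0.05 and NDRG1 at -0.39 ± 0.06.

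By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 761 of 14999 genes changed in untreated cells, 376 higher and 385 lower in 6KQ, of which 43 and 46 by 2-fold or more. With spike-in scaling 1336 changed, 1276 higher and 60 lower, which moved the share higher from 49.4% to 95.5%. The calls of UGDH, CCNG1, BTG2, PSPH, CBS, NR4A1, NDRG1, CDC25C, TPX2, CCNB1, H3C4, INSIG1, IDI1, NQO1, ICAM1, MED11, SDHD, COL1A1 and COL6A1 were lost with that scaling. Without untreated WT replicate 2 the count was 3511 (1881 higher, 1630 lower, of which 71 and 61 by 2-fold or more), and 748 of the 761 genes were among them with the same sign. Of 27 lists, 3 passed camera upward and 8 downward with 12 libraries, and 9 and 6 without that library. NRF2 and ATF4 genes no longer passed without it (adjusted p = 0.0936 and 0.0586), and 6 further lists passed upward. With an estimated correlation in addition, 3 calls became 5, with heat shock and autophagy genes gained (adjusted p = 0.0322 and 0.0364). It was 235, 276 or 262 without untreated 6KQ replicate 1, 2 or 3, and 502 or 504 without 6KQ replicate 1 or 2 after H2O2.

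The second question was the same contrast in cells given H2O2. Of the 12 genes that the naming rule gave there as largest rises and falls, 7 were also among the 12 of untreated cells. KRT81 rose by 2.64 ± 0.21, KRT86 by 1.98 ± 0.11, OLFML3 by 1.81 ± 0.06 (adjusted p = 7.76e-08), KRT17 by 1.76 ± 0.21 and ACTG2 by 1.63 ± 0.13, from 40.5 ± 1.00 to 126 ± 2.36 CPM (SD, n = 3). GAL, the neuropeptide galanin, rose by 1.41 ± 0.19. CLEC3A fell by 1.36 ± 0.16 (adjusted p = 0.000697), H19, an imprinted long noncoding RNA, by 1.01 ± 0.10, DOC2A, a calcium sensor, by 0.96 ± 0.10, AKR1C2 by 0.93 ± 0.13, KYNU, kynureninase, by 0.87 ± 0.07 and MARCHF8, a ubiquitin ligase, by 0.85 ± 0.12.

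After H2O2, p53 targets were lower in 6KQ than in WT cells. Of 40, 6 fell and 34 did not pass (11 fell adjusted over the list alone), among them SESN1, a stress-inducible mTORC1 regulator, by 0.32 ± 0.05, CCNG1 by 0.30 ± 0.05 and BTG2 by 0.34 ± 0.06. The median was -0.17 (camera adjusted p = 1.76e-07, and adjusted p = 0.0062 with an estimated correlation). Estrogen receptor targets were again higher, with 8 of 47 up and 39 not passing (14 rose and 1 fell adjusted over the list alone), and the list median was 0.14, or -0.16 with spike-in scaling (camera adjusted p = 2.3e-06, and adjusted p = 0.00478 with an estimated correlation). HSPB8 and AREG, an EGF receptor ligand, each rose by 0.81 ± 0.07 and PDZK1 by 0.71 ± 0.09. Of 47 S phase genes 5 rose and 42 did not pass (8 rose adjusted over the list alone), and the list median was 0.11, or -0.19 with spike-in scaling (camera adjusted p = 9.66e-06, and adjusted p = 0.0406 with an estimated correlation). The 5 that rose were E2F2 at 0.42 ± 0.07, CCNE1, cyclin E1, at 0.37 ± 0.08, MCM6, a replicative helicase subunit, at 0.23 ± 0.05 or -0.07 with spike-in scaling, ORC6 at 0.29 or -0.01 with spike-in scaling, and SLBP. In cholesterol synthesis 4 of 32 fell and 28 did not pass (7 fell adjusted over the list alone). The median was -0.10 (camera adjusted p = 0.0004, and adjusted p = 0.0147 with an estimated correlation). INSIG1 fell by 0.59 ± 0.05, LDLR, the LDL receptor, by 0.46 ± 0.09 and HMGCS1, HMG-CoA synthase, by 0.27 ± 0.06.

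Lists that passed camera after H2O2 and lost the call with an estimated correlation included replication-dependent histones, where 4 of 40 fell (14 adjusted over the list alone), among them H2BC5 by 0.76 ± 0.11, H2BC8 by 0.56 ± 0.11 and H2AC11 by 0.38 ± 0.08. The median was -0.34 (camera adjusted p = 3.11e-07, and adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes had 2 of 33 up, IFI27 and STAT1, the latter at 0.26 or -0.04 with spike-in scaling (3 adjusted over the list alone), and the list median was 0.26, or -0.04 with spike-in scaling (camera adjusted p = 6.65e-05, and adjusted p = 0.334 with an estimated correlation). ATF4 genes had 3 of 36 up (6 rose and 2 fell adjusted over the list alone), and the list median was 0.10, or -0.20 with spike-in scaling (camera adjusted p = 0.0022, and adjusted p = 0.44 with an estimated correlation). The 3 that rose were the stress factor ATF3 at 0.26 ± 0.06, WARS1, a tRNA synthetase, at 0.20 ± 0.05 and CEBPG at 0.24 ± 0.06, which with spike-in scaling stood at -0.04, -0.10 and -0.06. Of 38 immediate early genes 5 rose and 1, BTG2, fell (11 and 3 adjusted over the list alone), with KLF2 up by 0.58 ± 0.08 and JUN by 0.32 ± 0.05, and the list median was 0.12, or -0.18 with spike-in scaling (camera adjusted p = 0.00202, and adjusted p = 0.0651 with an estimated correlation). Of 21 basal markers 6 rose and 2 fell (7 and 2 adjusted over the list alone), LAMC2 rising by 1.25 ± 0.07 and CD44 by 0.52 ± 0.07, and the list median was 0.07, or -0.23 with spike-in scaling (camera adjusted p = 0.0298, and adjusted p = 0.103 with an estimated correlation). Heat shock, ribosome biogenesis and autophagy lists had medians of 0.09, 0.07 and 0.07, or -0.21, -0.23 and -0.23 with spike-in scaling (camera adjusted p = 0.000139, 0.00099 and 0.0043, and adjusted p = 0.362, 0.276 and 0.362 with an estimated correlation), with 2, 1 and 2 members up.

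The remaining lists did not pass after H2O2, among them Mediator subunits (adjusted p = 0.909), ribosomal proteins (adjusted p = 0.738), oxidative phosphorylation (adjusted p = 0.315) and G2 and M phase genes (median 0.03, or -0.27 with spike-in scaling; adjusted p = 0.249). Of the 51 G2 and M genes 0 passed by edgeR, 6 were higher and 4 lower at an unadjusted p under 0.05, and 1 was lower by DESeq2. NRF2 targets (median 0.02, or -0.27 with spike-in scaling; adjusted p = 0.695) split into 4 that rose and 4 that fell of 35, with SRXN1, sulfiredoxin, at 0.37 ± 0.07 and UGDH at -0.39 ± 0.06. Hypoxia targets (median 0.02, or -0.28 with spike-in scaling; adjusted p = 0.54) split into 4 that rose, such as ALDOC at 0.53, and 2 that fell. Of 30 luminal markers (adjusted p = 0.505) SPDEF stood at -0.43 ± 0.08 and ERBB2 at -0.18, and TFAP2A at 0.26, or -0.04 with spike-in scaling.

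After H2O2, 704 genes differed between the lines, 390 higher and 314 lower in 6KQ, of which 41 and 20 by 2-fold or more. With spike-in scaling 5103 differed, 80 higher and 5023 lower, which moved the share higher from 55.4% to 1.57%. The calls of SRXN1, KLF2, JUN, CD44, SLC2A1, ALDOC, E2F2, CCNE1 and SLBP were lost with that scaling. Without untreated WT replicate 2, which is in neither group compared here, the count was 4903 (2372 higher, 2531 lower, of which 62 and 51 by 2-fold or more), including all 704. Lists that passed camera went from 9 upward and 3 downward to 10 and 6, and all 12 passed again in the same direction. With an estimated correlation in addition, heat shock and autophagy genes passed (adjusted p = 0.0322 for each). It fell to 458 or 466 without untreated 6KQ replicate 1 or 3, to 263, 302 or 265 without WT replicate 1, 2 or 3 after H2O2, and to 291, 247 or 252 without 6KQ replicate 1, 2 or 3 after H2O2. Across 14999 genes the difference between the lines correlated between untreated and H2O2 cells, which share no libraries, with Pearson's r = 0.430 and Spearman's rho = 0.402, and genes are not independent replicates. A total of 171 genes were higher in both and 130 lower in both, against 9.78 and 8.06 for independent lists, and 1 was opposite. These numbers without untreated WT replicate 2 were 1153 and 997, against 294 and 272, and 71 were opposite. Both comparisons set the same lines against each other, so a lasting difference between the lines of any origin would give such overlap.

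The third question was how cells with WT MED1 responded to H2O2. The p53 targets rose together: 40 of 40 measured rose, also adjusted over the list alone, with a median of 1.55 (camera adjusted p = 1.37e-23, and adjusted p = 0.000194 with an estimated correlation). CDKN1A (Gene ID 1026, chromosome 6, 36676463 to 36687332), the p21 inhibitor of cyclin-dependent kinases, rose by 4.50 ± 0.07, from 76.0 ± 4.65 to 1717 CPM (adjusted p = 4.15e-12). FAS (Gene ID 355, chromosome 10, 88964050 to 89017059), a death receptor, rose by 4.25 ± 0.10 and SESN2, a stress-inducible mTORC1 regulator, by 2.35 ± 0.05. Genes of G2 and M phase fell, 50 of 51, also adjusted over the list alone, with a median of -1.22 (camera adjusted p = 1.12e-25, and adjusted p = 0.000194 with an estimated correlation). PLK1 (Gene ID 5347, chromosome 16, 23678889 to 23690367), a mitotic kinase, fell by 2.90 ± 0.06, from 227 ± 15.7 to 30.4 ± 0.868 CPM (adjusted p = 1.16e-10), DLGAP5, a spindle protein, by 2.45 ± 0.07 and AURKA, a mitotic kinase, by 2.18 ± 0.07. The antioxidant gene HMOX1 (Gene ID 3162, chromosome 22, 35381096 to 35394207), heme oxygenase, rose by 4.91 ± 0.12, from 7.72 ± 1.42 to 233 ± 16 CPM.

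The largest rises in WT cells by the naming rule were of genes with few counts before treatment. Their SE values derive from the F statistic and may understate the error at such counts. CPNE7, a calcium-binding copine, rose by 7.67 ± 0.38, from 4 counts summed over 3 untreated libraries to 881. SLC6A3 (Gene ID 6531, chromosome 5, 1392794 to 1445440), the dopamine transporter, rose by 6.99 ± 0.32, from 4 counts to 548. LHFPL3-AS2, an antisense long noncoding RNA, rose by 7.07 ± 0.20, MYH15, a myosin, by 6.43 ± 0.29, COL20A1, a collagen, by 5.99 ± 0.24 and SERPINB5, maspin, by 5.89 ± 0.27. The strand setting of the counting is not given in the sources used here, so antisense values are uncertain. Besides PLK1 and DLGAP5 the largest falls by the naming rule were PIF1 (Gene ID 80119, chromosome 15, 64815632 to 64827062), a DNA helicase, at -3.47 ± 0.16, TNFAIP8L1 at -3.07 ± 0.15, PSRC1, a microtubule regulator, at -2.60 ± 0.12 and NXPH3 at -2.31.

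In WT cells 26 of 38 immediate early genes rose and 4 fell, as adjusted over the list alone, with FOSL1, an AP-1 subunit, up by 4.63 ± 0.17. The median was 0.57 (camera adjusted p = 1.99e-07, and adjusted p = 0.00774 with an estimated correlation). Of 47 S phase genes 1 rose, E2F7, and 40 fell, as adjusted over the list alone, including POLE2, a DNA polymerase subunit, by 1.43 and CDC6, a replication licensing factor, by 0.97. The median was -0.51 (camera adjusted p = 1.36e-11, and adjusted p = 0.00719 with an estimated correlation). Of 32 cholesterol genes 2 rose, FADS1 and FADS2, and 22 fell, as adjusted over the list alone, SQLE, squalene epoxidase, by 0.95 ± 0.06. The median was -0.46 (camera adjusted p = 5.03e-06, and adjusted p = 0.00683 with an estimated correlation). Of 45 DNA repair genes 4 rose and 27 fell (4 and 28 adjusted over the list alone). The median was -0.38 (camera adjusted p = 5.84e-05, and adjusted p = 0.00719 with an estimated correlation). XPC and DDB2, damage sensors of nucleotide excision repair, each rose by 1.38. Of 47 estrogen receptor targets 8 rose and 25 fell (8 and 26 adjusted over the list alone), with SGK3, a kinase, at -1.20 and STC2, a secreted glycoprotein, at 1.29. The median was -0.32 (camera adjusted p = 0.00398, and adjusted p = 0.0282 with an estimated correlation).

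Further lists passed camera in WT cells and lost the call with an estimated correlation. Of 35 NRF2 targets 26 rose and 1, CBR1, fell, as adjusted over the list alone, with OSGIN1, an oxidative stress growth inhibitor, up by 2.22 ± 0.11. The median was 0.88 (camera adjusted p = 3.14e-10, and adjusted p = 0.102 with an estimated correlation, or 0.0123 without untreated WT replicate 2). Of 36 ATF4 genes 31 rose and 2 fell, as adjusted over the list alone, with ATF3 up by 2.86 ± 0.07 and DDIT4 by 2.88 ± 0.09. The median was 0.74 (camera adjusted p = 1.36e-11, and adjusted p = 0.0762 with an estimated correlation). Of 30 apoptosis regulators 17 rose and 6 fell, as adjusted over the list alone, with TNFRSF10B, a death receptor, up by 2.17. The median was 0.32 (camera adjusted p = 0.00419, and adjusted p = 0.0704 with an estimated correlation). Of 21 basal markers 11 rose and 4 fell (13 and 4 adjusted over the list alone), with SERPINE1, a plasminogen activator inhibitor, up by 4.60 ± 0.16 and AXL, a receptor tyrosine kinase, by 3.93. The median was 0.36 (camera adjusted p = 0.0108, and adjusted p = 0.0651 with an estimated correlation). Of 12 nuclear long noncoding RNAs 7 rose (8 adjusted over the list alone), such as HCG11 by 0.71. The median was 0.40 (camera adjusted p = 0.0285, and adjusted p = 0.109 with an estimated correlation). Luminal markers fell in 16 of 30 and rose in 4, as adjusted over the list alone, with AGR3 at -1.93 and ELF3, an epithelial transcription factor, at 0.83. The median was -0.22 (camera adjusted p = 0.0313, and adjusted p = 0.158 with an estimated correlation). Of 25 heat shock genes 4 rose and 14 fell (5 and 14 adjusted over the list alone), with DNAJB4 at 2.20 and HSPA8 at -1.13. The median was -0.28 (camera adjusted p = 0.0364, and adjusted p = 0.615 with an estimated correlation). Of 40 histone genes 2 rose and 16 fell (2 and 14 adjusted over the list alone). The median was -0.45 (camera adjusted p = 0.0108, and adjusted p = 0.602 with an estimated correlation). Of 47 ribosome biogenesis genes 3 rose and 21 fell, as adjusted over the list alone, with UBTF, the ribosomal DNA factor, at -0.66. The median was -0.25 (camera adjusted p = 0.00814, and adjusted p = 0.375 with an estimated correlation). Of 75 oxidative phosphorylation genes 11 fell (3 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.0191, and adjusted p = 0.833 with an estimated correlation), and 0.08 without untreated WT replicate 2. The ribosomal protein list had a median of -0.11 (adjusted p = 0.472), and 0.20 without that library (adjusted p = 5.17e-12; 70 of 78 up).

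Lists that did not pass in WT cells were unfolded protein response chaperones (3 of 22 rose, 13 fell, adjusted p = 0.0768), with HERPUD1 at 0.90 and PDIA4 at -0.45, NF-kB genes (7 of 16 rose, 3 fell, median 0.18, or -0.05 with spike-in scaling, adjusted p = 0.182), with the cytokines LIF at 4.91 ± 0.13 and CSF1 at 3.81, interferon-stimulated genes (2 of 33 rose, 9 fell, adjusted p = 0.459), with USP18 at -0.57, and Mediator subunits (5 of 33 rose, 10 fell, adjusted p = 0.466), with MED21 at -0.86 ± 0.08 and MED9 at 0.53 ± 0.08. Autophagy genes (14 of 38 rose, 5 fell, median 0.06, or -0.18 with spike-in scaling, adjusted p = 0.22) included GABARAPL1 at 2.04, hypoxia targets (10 of 40 rose, 13 fell, adjusted p = 0.996) included VEGFA at 1.06, and the metallothionein and zinc list (3 of 6 rose, median 0.17, or -0.07 with spike-in scaling, adjusted p = 0.476) included the zinc exporter SLC30A1 at 0.66. Of 7 leukocyte and endothelial markers 3 rose (adjusted p = 0.211), ITGAM by 4.65, CSF1R by 3.09 and LYZ by 1.31. Of 8 non-polyadenylated RNAs 0 passed by edgeR, by DESeq2 or at an unadjusted p under 0.05 (adjusted p = 0.538), and they took 0.00387% to 0.0134% of human counts in all libraries.

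By the same test 8207 of 14999 genes changed with H2O2 in WT cells, 4067 higher and 4140 lower, of which 1745 and 354 by 2-fold or more. With spike-in scaling 8977 changed, 2382 higher and 6595 lower, which moved the share higher from 49.6% to 26.5%. Without untreated WT replicate 2 the count was 10736 (5402 higher, 5334 lower), and lists that passed camera went from 7 upward and 10 downward to 9 and 8. Histone, heat shock and oxidative phosphorylation genes no longer passed (adjusted p = 0.202, 0.0747 and 0.115), while ribosomal proteins and autophagy passed upward and unfolded protein response chaperones downward. With an estimated correlation and that library left out, DNA repair genes and estrogen receptor targets also lost the call (adjusted p = 0.0535 and 0.0925). The calls of SLC39A10, FADS1, LYZ and NORAD were lost with spike-in scaling, and that of LYZ also without untreated WT replicate 2 or 3 (1.01 and 1.18) or WT replicate 1 or 3 after H2O2 (1.29 and 1.17).

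The fourth question was the response to H2O2 in cells with 6KQ MED1. All 40 p53 targets rose, also adjusted over the list alone. The median was 1.41 (camera adjusted p = 1.37e-22, and adjusted p = 0.000194 with an estimated correlation). CDKN1A rose by 4.52 ± 0.07, from 67.1 to 1538 CPM (adjusted p = 4.02e-12), FAS by 4.50 ± 0.10 and SESN2 by 2.35 ± 0.05. Of 51 G2 and M phase genes 50 fell, also adjusted over the list alone, PLK1 by 2.47 ± 0.06, DLGAP5 by 1.95 ± 0.07 and KIF20A, a mitotic kinesin, by 2.08 ± 0.08. The median was -1.03 (camera adjusted p = 1.21e-23, and adjusted p = 0.000194 with an estimated correlation). HMOX1 rose by 4.95 ± 0.12, from 7.91 ± 0.53 to 244 ± 9.87 CPM (SD, n = 3). The largest rises by the naming rule were SLC6A3 at 7.06 ± 0.32, from 4 counts summed over 3 untreated libraries to 574, CPNE7 at 7.01 ± 0.38, antisense LHFPL3-AS2 at 6.87 ± 0.19, MYH15 at 6.69 ± 0.28, TNXB, a tenascin, at 6.27 ± 0.20 and COL20A1 at 5.94 ± 0.26. PIF1 fell by 3.64 ± 0.18, TNFAIP8L1 by 2.62 ± 0.17, PLEKHS1 by 2.69 ± 0.14, NXPH3 by 2.57 ± 0.11 and B3GALT5, a galactosyltransferase, by 2.41 ± 0.24.

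In 6KQ cells 30 of 38 immediate early genes rose and 5 fell (31 and 5 adjusted over the list alone), FOSL1 rising by 4.55 ± 0.18, and the list median was 0.70, or -0.09 with spike-in scaling (camera adjusted p = 3.62e-08, and adjusted p = 0.00719 with an estimated correlation). Of 47 S phase genes 2 rose, E2F7 and PCNA, the latter by 0.27, or -0.52 with spike-in scaling, and 36 fell (2 and 37 adjusted over the list alone), POLE2 by 1.42. With that scaling 0 of the 47 rose and 46 fell. The median was -0.40 (camera adjusted p = 1.05e-09, and adjusted p = 0.00874 with an estimated correlation). Of 32 cholesterol genes 2 rose, FADS2 and FADS1, the latter by 0.75, or -0.04 with spike-in scaling, and 20 fell (2 and 21 adjusted over the list alone), INSIG1 by 1.04 and SQLE by 0.95 ± 0.06. The median was -0.32 (camera adjusted p = 2.27e-05, and adjusted p = 0.00719 with an estimated correlation). Of 45 DNA repair genes 4 rose and 26 fell (5 and 27 adjusted over the list alone), with CHEK1, a checkpoint kinase, at -0.83 and XPC at 1.26. The median was -0.39 (camera adjusted p = 8.55e-05, and adjusted p = 0.00774 with an estimated correlation). Of 47 estrogen receptor targets 7 rose and 30 fell, as adjusted over the list alone, SGK3 by 1.37. The median was -0.42 (camera adjusted p = 0.00015, and adjusted p = 0.00819 with an estimated correlation).

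The calls of the following lists in 6KQ cells were lost with an estimated correlation. Of 35 NRF2 targets 30 rose (31 adjusted over the list alone), with SRXN1 up by 1.73 ± 0.07, and the list median was 0.77, or -0.03 with spike-in scaling (camera adjusted p = 1.57e-12, and adjusted p = 0.0704 with an estimated correlation, or 0.0127 without untreated WT replicate 2). Of 36 ATF4 genes 33 rose (34 adjusted over the list alone), with DDIT4 up by 3.35 ± 0.09 and ATF3 by 3.07 ± 0.07. The median was 0.94 (camera adjusted p = 1.9e-14, and adjusted p = 0.0559 with an estimated correlation). Of 21 basal markers 15 rose and 4 fell, as adjusted over the list alone, with SERPINE1 up by 3.73 ± 0.15, and the list median was 0.51, or -0.28 with spike-in scaling (camera adjusted p = 0.00722, and adjusted p = 0.0567 with an estimated correlation). Of 30 apoptosis regulators 15 rose and 3, BCL2, CASP6 and CASP9, fell, as adjusted over the list alone, with BBC3, a pro-apoptotic BH3 protein, up by 2.94 and TNFRSF10B by 2.18, and the list median was 0.27, or -0.52 with spike-in scaling (camera adjusted p = 0.00132, and adjusted p = 0.0555 with an estimated correlation). Luminal markers rose in 3 of 30 and fell in 13, as adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.0269, and adjusted p = 0.148 with an estimated correlation). Unfolded protein response chaperones rose in 2 of 22 and fell in 10, as adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.0322, and adjusted p = 0.196 with an estimated correlation). Of 40 histone genes 3 rose and 14 fell (3 and 13 adjusted over the list alone). The median was -0.43 (camera adjusted p = 0.0198, and adjusted p = 0.621 with an estimated correlation). Ribosomal proteins had a median of 0.23, or -0.57 with spike-in scaling (camera adjusted p = 0.0269, and adjusted p = 0.838 with an estimated correlation); 0 of 78 passed by edgeR or DESeq2, and 2 were higher at an unadjusted p under 0.05.

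Lists that did not pass in 6KQ cells were NF-kB genes (9 of 16 rose, 5 fell, median 0.46, or -0.33 with spike-in scaling, adjusted p = 0.164), with LIF at 4.36 ± 0.13, interferon-stimulated genes (3 of 33 rose, 7 fell, adjusted p = 0.143), with RIGI at -0.96, Mediator subunits (7 of 33 rose, 9 fell, adjusted p = 0.634), with MED21 at -0.96 ± 0.08 and MED9 at 0.76 ± 0.08 or -0.04 with spike-in scaling, and leukocyte and endothelial markers (3 of 7 rose, median 0.45, or -0.33 with spike-in scaling, adjusted p = 0.237), with ITGAM at 5.26. Autophagy genes (14 of 38 rose, 4 fell, median 0.10, or -0.70 with spike-in scaling, adjusted p = 0.0631) included TFE3 at 0.65, or -0.15 with spike-in scaling, and heat shock genes (5 of 25 rose, 9 fell, adjusted p = 0.237) included HSPB8 at 1.63. The long noncoding RNAs (6 of 12 rose, 1 fell, median 0.39, or -0.40 with spike-in scaling, adjusted p = 0.135) included HCG11 at 0.71 and SNHG1 at 0.41, or -0.08 and -0.39 with spike-in scaling. Hypoxia targets, the metallothionein and zinc list and oxidative phosphorylation did not pass either, with medians of 0.12, 0.14 and 0.08, or -0.68, -0.66 and -0.72 with spike-in scaling (adjusted p = 0.601, 0.542 and 0.848). Ribosome biogenesis (adjusted p = 0.0836) and non-polyadenylated RNA (adjusted p = 0.909) also did not pass.

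In 6KQ cells 7874 genes changed with H2O2, 4043 higher and 3831 lower, of which 1781 and 399 by 2-fold or more. With spike-in scaling 12661 changed, 1350 higher and 11311 lower, which moved the share higher from 51.3% to 10.7%. The calls of HERPUD1, ELF3, TGFBI, CSF1R, LYZ, VEGFA, E2F7, FADS2, FLCN and GAS5 were lost with that scaling. Without untreated WT replicate 2 the count was 11184 (5545 higher, 5639 lower), and lists that passed camera went from 7 upward and 8 downward to 9 and 7, with histones lost (adjusted p = 0.0828) and autophagy and nuclear long noncoding RNA added upward. With an estimated correlation in addition, DNA repair genes and estrogen receptor targets lost the call (adjusted p = 0.0571 and 0.059).

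**Figure D3:**
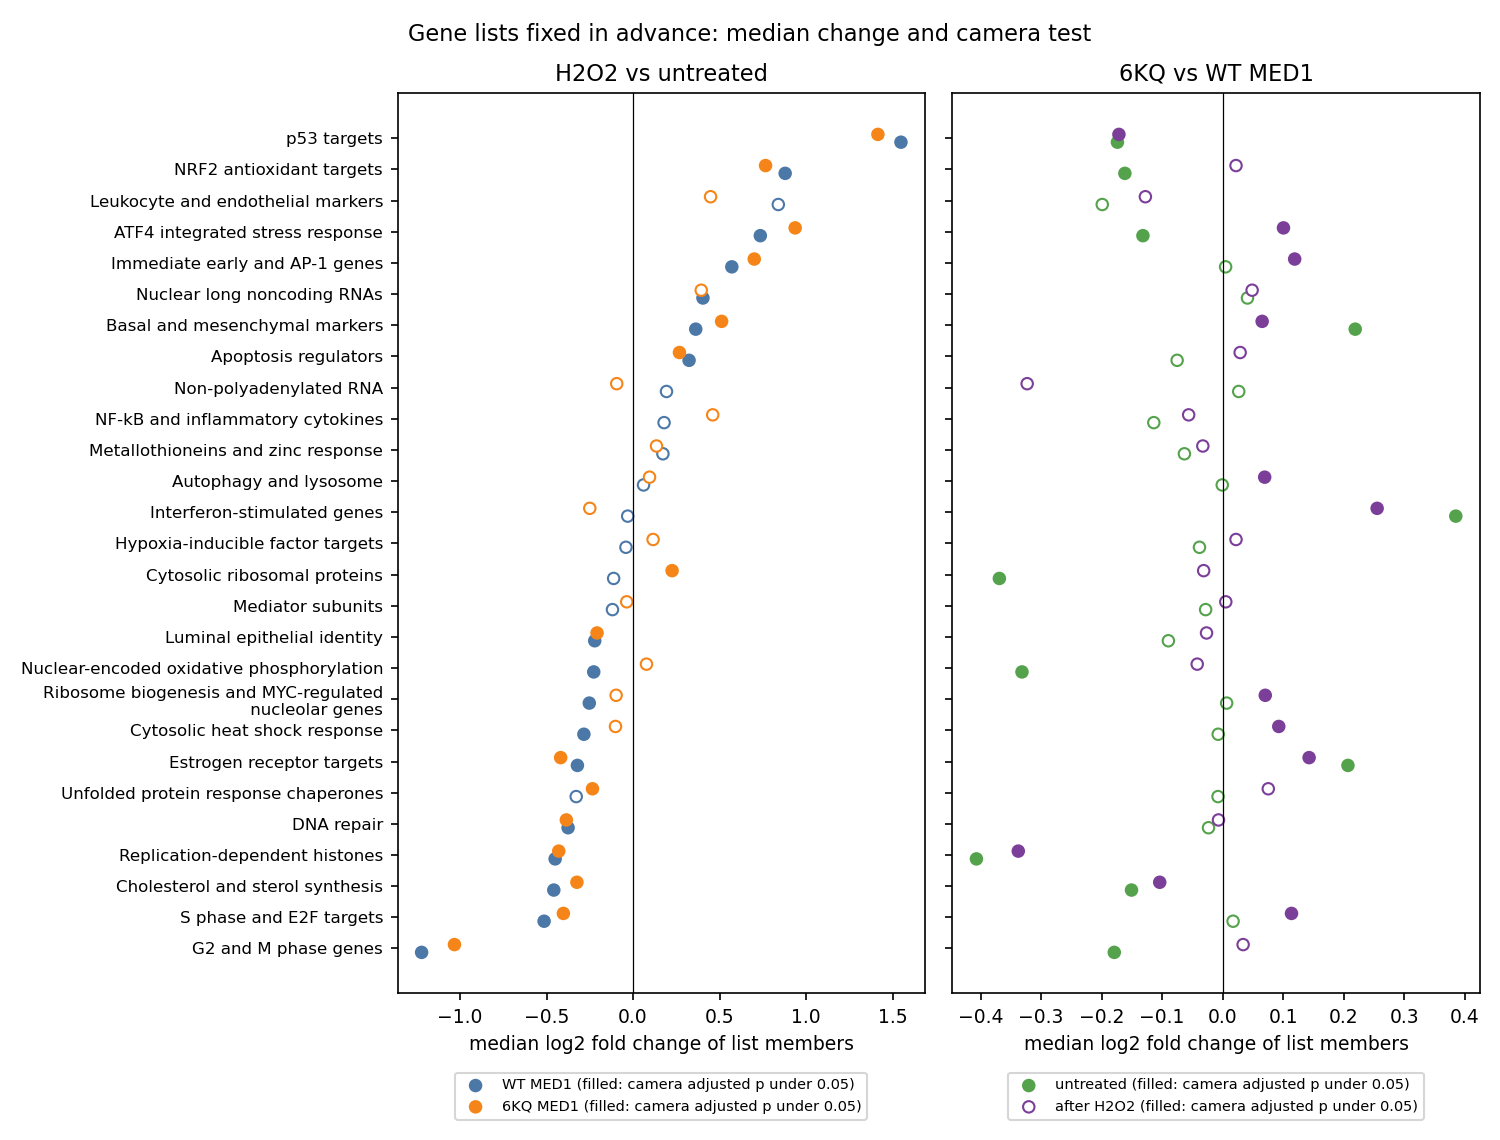
Each point is the median log2 fold change of 1 fixed gene list, after H2O2 against untreated in each line (left) and 6KQ against WT in each treatment (right), and filled points passed camera. The p53 targets had medians of 1.55 and 1.41 and the G2 and M phase genes -1.22 and -1.03 with H2O2 in WT and 6KQ cells; with spike-in scaling the medians of several lists that lie nearer 0 turn sign.

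The fifth question was whether the response to H2O2 differed between the lines. Across 14999 genes the responses of the lines, which share no libraries, correlated with Pearson's r = 0.941 and Spearman's rho = 0.895 and a slope of 0.943 for 6KQ on WT. A total of 3415 genes rose in both lines and 3192 fell in both, against 1096 and 1057 for independent lists, and 6 were opposite. With untreated WT replicate 2 left out, 4759 rose in both and 4841 fell in both, against 1973 and 1981, and 23 were opposite. The interaction passed for 2 genes. NUTM2B (Gene ID 729262, chromosome 10, 79692115 to 79712758), a member of a family of near-identical copies, rose more in 6KQ cells by 1.43 ± 0.18 (adjusted p = 0.0408), from 0.513 to 8.60 CPM against 1.13 to 6.99 CPM in WT cells. C1QTNF6 (Gene ID 114904, chromosome 22, 37180166 to 37199423), a secreted C1q-related protein, differed by -0.93 ± 0.11 (adjusted p = 0.0286), from 17.2 to 19.6 CPM in 6KQ cells against 9.95 to 21.6 CPM in WT cells. MED1 did not pass, at -0.20 ± 0.27 (adjusted p = 0.822), 0.04 without untreated WT replicate 2 (adjusted p = 0.646) and -0.72 with spike-in scaling (adjusted p = 0.0567).

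**Figure D4:**
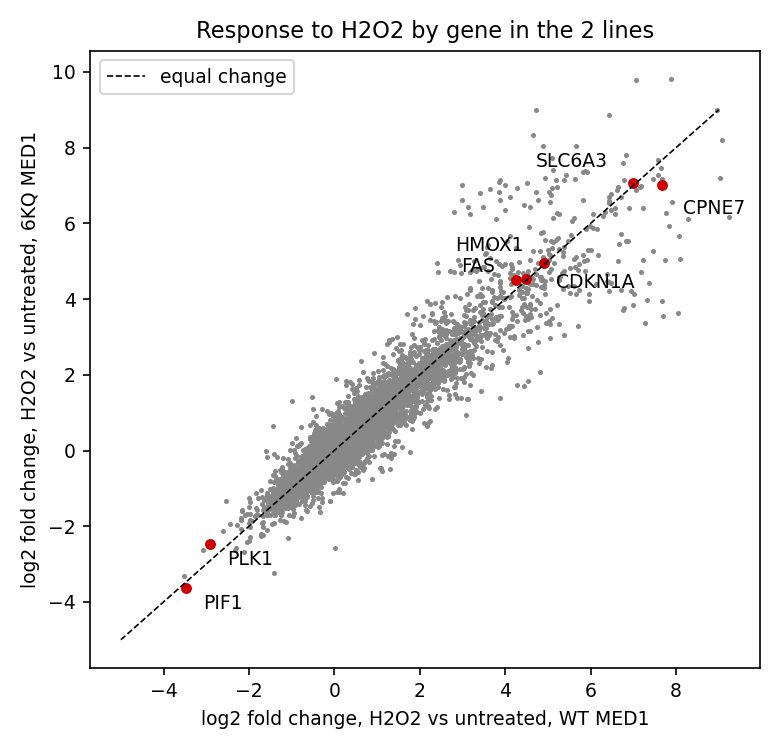
Each point is 1 of 14999 tested genes, with its log2 fold change after H2O2 in WT cells on the horizontal axis and in 6KQ cells on the vertical axis, and the dashed line marks equal change. The genes lie along that line with r = 0.941 and a slope of 0.943.

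As a group, G2 and M phase genes fell less in 6KQ cells relative to the bulk of mRNA, with an interaction median of 0.21 (camera adjusted p = 8.53e-14, and adjusted p = 0.000949 with an estimated correlation), or -0.33 with spike-in scaling. Of these 51 genes 10 were higher adjusted over the list alone. With TMM scaling 11 of the 51 were lower in 6KQ than in WT cells untreated, and 0 passed between the lines after H2O2. The smaller fall thus went with a lower starting level in 6KQ cells. Estrogen receptor targets had a median of -0.09 (1 higher and 1 lower of 47 adjusted over the list alone, camera adjusted p = 0.00169, and adjusted p = 0.019 with an estimated correlation). The ATF4 list had a median of 0.22, or -0.34 with spike-in scaling (2 of 36 higher adjusted over the list alone, camera adjusted p = 6.58e-10, and adjusted p = 0.103 with an estimated correlation). NRF2 targets, S phase, immediate early, heat shock and ribosome biogenesis genes had medians of 0.15, 0.12, 0.10, 0.09 and 0.09, or -0.41, -0.45, -0.47, -0.46 and -0.47 with spike-in scaling (camera adjusted p = 1.96e-05, 0.00178, 0.025, 0.00463 and 0.0278, and adjusted p = 0.276, 0.109, 0.158, 0.507 and 0.492 with an estimated correlation). Ribosomal protein and oxidative phosphorylation lists had medians of 0.34 and 0.30, or -0.25 and -0.28 with spike-in scaling (camera adjusted p = 2.84e-10 and 8.46e-08, and adjusted p = 0.589 and 0.615 with an estimated correlation), and 0.01 and -0.01 without untreated WT replicate 2. Lists that passed went from 9 upward and 1 downward with 12 libraries to 4 upward and 6 downward without that library. The 5 that no longer passed were heat shock, immediate early, ribosome biogenesis, ribosomal protein and oxidative phosphorylation genes (adjusted p = 0.326, 0.216, 0.462, 0.18 and 0.527). The 5 that passed only without it, all downward, were p53 targets, interferon-stimulated genes, luminal markers, unfolded protein response chaperones and non-polyadenylated RNA, with medians of -0.10, -0.18, -0.05, -0.03 and -0.99, and of these luminal markers also passed with an estimated correlation (adjusted p = 0.0498). The non-polyadenylated RNAs were listed as a sign of RNA selection and took only 0.00387% to 0.0134% of human counts. With 12 libraries 0 of the 8 measured had an unadjusted interaction p under 0.05 by edgeR. In that fit the p53 targets did not pass camera (median -0.02, adjusted p = 0.0636), nor did the other 16 lists (adjusted p of 0.142 to 0.84).

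Of 14999 genes 1010 had an unadjusted interaction p under 0.05 (2656 of 15180 without untreated WT replicate 2), and DESeq2 called 46. With no interaction in any gene, a share of about 0.05 of the tested genes would fall under that unadjusted bound. The edgeR count of 2 became 743 without untreated WT replicate 2 (330 higher, 413 lower), 1 without untreated WT replicate 1 or WT replicate 2 after H2O2, and 0 without any other single library. With spike-in scaling it was 8729, of which 8 higher and 8721 lower (0.0916% higher, against 50% of 2). Chosen after their values were seen, 6 genes of the G2 and M and estrogen receptor lists passed without replicate 2: CENPF, a kinetochore protein, at 0.51, TPX2 at 0.29 and CCNB1 at 0.35 (adjusted p = 2.60e-06, 3.22e-06 and 9.67e-07), AREG at 0.40, CCND1, cyclin D1, at -0.26 and NHERF1 at -0.18 (adjusted p = 1.43e-07, 1.05e-05 and 0.000604). With 12 libraries these stood at 0.31, 0.30, 0.49, 0.52, -0.34 and -0.05 (adjusted p = 0.769, 0.311, 0.386, 0.283, 0.551 and 0.883), and the first 4 at -0.21, -0.25, -0.07 and -0.04 with spike-in scaling.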

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

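The tests of transcript length, of the MED1 percentile, of another group's label, of independent spike-in errors and of cell number or RNA input were chosen only after the result was seen; so was the fit without untreated WT replicate 2 combined with other settings. The bound of the label score was changed more than once after its value was seen.

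Untreated WT replicate 2 differed from replicates 1 and 3 in many genes. A label from another group of the series is argued against by scores that ran from untreated WT at 0 to the other side at 1. For the MED1 form its score was 0.279, against 0.872 to 1.01 in 6KQ libraries. For H2O2 it was 0.0361, against at least 0.950 in H2O2 libraries. Untreated WT replicates 1 and 3, which set the 0, had MED1-form scores of 0.0158 and -0.0158, and WT libraries after H2O2 had 0.248 to 0.290. With its length and GC trend removed this library stood at 0.251. The scores speak only to a whole library of another group, and a sample from outside these groups stays open. A length bias is a candidate cause: across genes the deviation of this library fell with transcript length (Spearman's rho = -0.588), from a median of 0.62 at 500 to 1000 nucleotides to -0.55 above 8000 nucleotides. The 137 genes below 500 nucleotides had a lower median of 0.41, and genes are not independent replicates. An effect on all RNA in the tube is also a candidate. The chi-square of the spike-in counts of this library against replicates 1 and 3 was 3.03 and 3.17, while all other pairs were at most 1.08. Human counts thinned to the spike-in depth gave 2.84 and 2.57 for the same pairs, a comparison added after the spike-in result. At like depth the spike-in thus departed no less than the human RNA. Its lower MED1 count (percentile 2.5 among 200 genes of like length and GC content) is not decided, so a real fall of MED1 in that sample stays open.

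By the interaction test, the response to H2O2 differed between lines in C1QTNF6 at -0.93 and NUTM2B at 1.43, and in the medians of 10 lists: NRF2 targets 0.15, ATF4 genes 0.22, heat shock 0.094, immediate early genes 0.10, estrogen receptor targets -0.090, S phase 0.12, G2 and M phase 0.21, ribosome biogenesis 0.087, ribosomal proteins 0.34 and oxidative phosphorylation 0.30. Of these 10 list calls 2 held with an estimated correlation, those of G2 and M phase genes and of estrogen receptor targets. With spike-in scaling the medians of the 9 upward lists were negative, as was the median of all genes, at -0.54. Camera, which sets a list against the other genes, was not run with that scaling. Without untreated WT replicate 2, 5 of the 10 passed again, all in the same direction, and 5 did not. The splits of the samples do not exclude chance for the gene count: 6 of 100 gave at least the real count of 2, and the highest of the others gave 1913. Of the 5 others that reached it, 4 exchanged the MED1 labels of all H2O2 libraries (7 to 1913 genes) and 1 kept the labels of untreated libraries (4 genes). All 5 thus held the difference between the lines within a treatment, a structure of the samples, so this share does not measure chance alone. For ribosomal proteins and oxidative phosphorylation the values without untreated WT replicate 2 were 0.01 and -0.01.

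Human counts per spike-in count fell after H2O2, with a difference of -0.50 on the log2 scale between 6KQ and WT cells. Independent errors in adding the spike-in to each library, with no difference between the lines in either treatment, are argued against by the exact permutation p of 0.005. That test shuffled the line labels within each treatment, so it does not test equal change with H2O2 alone. A difference of cell number or RNA input between whole groups could give the same value of -0.50 and stays open, since no cell number or RNA mass per library is in the tables. A larger loss of mRNA per cell in 6KQ cells is the biological hypothesis that the design names, and it stays open and untested.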

How the results depend on the processing

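Chosen only after the data were seen were voom weights and the settings that leave out untreated WT replicate 2 together with another change. Unless a reason is given, the cause was not tested.

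Both counts of genes changed with H2O2 stayed within 1.5 times of 8207 (WT) and 7874 (6KQ) without any single library (7118 to 10736 and 6857 to 11184). They were 5078 and 5071 against a fold change of 1.2, a stricter hypothesis by construction, and the 6KQ count was 12661 with spike-in scaling and 13247 with that library also left out. The untreated count of 761 for 6KQ against WT ranged from 235 to 3511 over single libraries left out. It was 1258 by DESeq2, 1336 with spike-in scaling, 38 with the compared groups alone, 127 against a fold change of 1.2, 2956 with voom weights, 2800 with spike-in scaling and replicate 2 out, and 3407 with the compared groups alone and replicate 2 out. After H2O2 the count of 704 ranged from 247 to 4903 and was 5103 with spike-in scaling, 5051 with the compared groups alone, 117 against a fold change of 1.2, 4777 with voom weights and 10145 with spike-in scaling and replicate 2 out. The interaction count of 2 ranged from 0 to 743 and was 46 by DESeq2, 8729 with spike-in scaling, 6 with the stricter filter, 0 against a fold change of 1.2, 453 with voom weights and 10791 with spike-in scaling and replicate 2 out. The common dispersion was 0.00888 with all 12 libraries and 0.000610 without untreated WT replicate 2, whose voom weight was 0.0290 (others 0.942 to 1.55), so that library set the spread that limits these counts.

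Replicate numbers were not shown to pair the samples: over 18 same-numbered pairs the correlation of deviations ran from -0.0586 to 0.0429, 0 pairs exceeded 0.1, and 4 libraries correlated best with their own number. With the number as a block the counts were 490, 450, 7915, 7668 and 0 in the order untreated, after H2O2, H2O2 in WT, H2O2 in 6KQ and interaction, where the 0 stands against 1010 genes at an unadjusted p under 0.05 by edgeR (2656 without untreated WT replicate 2) and 46 by DESeq2 without the block. Chance alone would put a share of about 0.05 of the tested genes under that unadjusted bound.

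MED1 after H2O2 stood at 0.072 with the compared groups alone (adjusted p = 0.047). With H2O2 in WT cells it ranged from -0.091 to 0.31 over single libraries left out, and in 6KQ cells it was -0.84 with spike-in scaling. The correlation of 0.941 between responses ranged from 0.919 to 0.939 over libraries left out and was 0.950 over genes called in either line, and the slope of 0.943 ranged from 0.883 to 0.958. The calls of 11, 12, 17, 15 and 10 lists became 3, 4, 7, 7 and 2 with an estimated correlation, and 5, 6, 6, 6 and 3 with replicate 2 also left out. Adjusted p turned with direction for ribosomal proteins under H2O2 in WT cells (5.17e-12 without replicate 2; 5.17e-12 to 0.491 over libraries), for oxidative phosphorylation there (0.115, and 0.419 with an estimated correlation; 0.000114 to 0.115) and in the interaction (0.527 and 0.725; 1.19e-12 to 0.527).

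Of 247 results for named genes, spike-in scaling reversed 11, weakened 31 and strengthened 2 (CCND1 at -0.88 and NHERF1 at -0.62 in the interaction). Reversed were CMBL at 0.051 and ERBB2 at 0.068 untreated, ATF3 at -0.035, WARS1 at -0.10, CEBPG at -0.055, TFAP2A at -0.040 and MCM6 at -0.066 after H2O2, and MED9 at -0.036, TFE3 at -0.15, HCG11 at -0.079 and SNHG1 at -0.39 for H2O2 in 6KQ cells. Calls lost numbered 51 against a fold change of 1.2, 33 of 237 with the compared groups alone, 13 with the block, 9 without a filter, 2 with upper-quartile scaling, 1 with DESeq2, 1 of 234 with the stricter filter and 1 to 20 over single libraries left out. None changed with RLE scaling or non-robust dispersion. NUTM2B ranged from 0.88 to 1.5 (adjusted p = 0.00143 to 0.266) and C1QTNF6 from -1.48 to -0.86 (adjusted p = 6.48e-11 to 0.171), each passing in 9 of 21 alternatives.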

Other observations

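Only tests with bounds written before the result was seen are reported in this part, except that the thresholds defining a nearly silent gene were set when the test was coded and the spike-scaled fold changes were tabulated with the results.

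Genes nearly silent before treatment appeared after H2O2 in both lines. Of 10623 genes with a mean below 0.2 CPM untreated, 261 rose, each with at least 10 more counts in every H2O2 library, by a median of 4.61 in WT and 4.53 in 6KQ cells on the log2 scale. They included SLC6A3, the dopamine transporter, CPNE7, a copine, and MYH15, a myosin. With spike-in scaling the medians were 4.38 and 3.78. That scaling moved the median of all genes by -0.24 in WT and -0.79 in 6KQ cells. A smaller RNA pool of that size does not account for rises this large. The genes were chosen for rising, so their medians could hardly have come near no change and are no separate test. Genomic DNA carried into the H2O2 libraries would raise silent genes in general, and 2.46% of them rose. A rise needed at least 10 more counts in every H2O2 library, so DNA at a lower level would be missed. Human genes detected per library were 17212 to 17377 untreated and 18613 to 18755 after H2O2, and a low level of DNA stays open. Transcription running on from an expressed gene upstream is a candidate explanation for part of the genes that rose: 8.81% of 488 silent genes within 10000 bp downstream of an expressed gene on the same strand rose, against 2.15% of 9707 others (odds ratio 4.39, 95% interval 3.04 to 6.21, Fisher's exact p = 1.89e-13), and the odds ratio for a neighbour on the opposite strand was 2.10 (1.30 to 3.24), while 209 of the 252 rising genes with a position had no same-strand neighbour. Induction by H2O2, the biological explanation that the design names, stays open.

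The splits of 6 samples are too few for a share under 0.05, since 3 against 3 make 10 splits. The real split was the 1 with the highest count in each comparison: 761 against a highest other of 1 untreated, 704 against 0 after H2O2, 8207 against 0 for H2O2 in WT cells and 7874 against 0 for H2O2 in 6KQ cells. Every other split mixed the groups compared, so their difference entered the spread within groups. The low counts were therefore close to fixed in advance and are no support for the real split.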
